A study of Homo sapiens with 4 samples.

How the data were processed

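RNA sequencing was done on MDA-LM2 cells, a human breast cancer line selected for lung metastasis from MDA-MB-231. Per the labels' protocols, cells were transfected by lipofection with either an RNA called the SSE mimetic or a scrambled oligo. Total RNA was extracted on columns with DNase treatment, and libraries were made with ScriptSeq v2 reagents. Each group had 2 samples, 4 in all, and the labels do not say whether the samples of a group came from separate cultures.

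Per the submitters' processing notes, reads were aligned with STAR 2.7 and the genome build was hg38. Per the file headers and layout, the deposited tables are skipped-exon summaries from MISO, a program that estimates how often a cassette exon is kept, with 1 summary per group and 1 comparison of the groups. The MISO version, its set of events and the way in which the samples of a group were combined are not given in the sources used here. The deposited percent spliced in (Ψ) is a fraction between 0 and 1, the posterior mean for the inclusion isoform, with a 95% credible interval from the authors' run. The deposited Bayes factor is a ratio, the weight of evidence for a difference over that for none, and was capped by the authors' program at 1e12. The deposited difference is Ψ in the SSE mimetic group minus Ψ in the scrambled group. In all 45977 events of the comparison it matched the difference between the group summaries to within 0.005, and the Ψ of the comparison's first sample was that of the SSE mimetic summary.

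The authors' tables also give, per event, the number of reads in other units, as text: reads that match the inclusion isoform alone (inclusion reads), the exclusion isoform alone (reads across the skipping junction), both isoforms (shared reads) or neither. MISO infers Ψ from inclusion, skipping and shared reads together, so a Ψ below 1 can arise without any skipping read when shared reads are plentiful. Since each group was 1 pooled read set, there is no spread between replicates, no test across samples and no value per sample. Credible and binomial intervals cover counting error only, and reads without molecular identifiers are not independent molecules. Binomial intervals over exons also treat exons as independent, although some overlap and share reads or lie in the same gene, so they can be too narrow.

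Events were listed with 1-based hg38 coordinates and were matched to GENCODE release 29. Of the 45977 events present in both summaries, 95.7% had a skipped exon with the exact coordinates of an annotated exon, 3.88% were assigned to a gene through the flanking exons and 0.442% were assigned to none. Events that shared a skipped exon were reduced to the event with the most isoform-specific reads (inclusion plus skipping), which left 39120 exons. An exon was tested when it had at least 10 isoform-specific reads in each group. It was called when the authors' Bayes factor was at least 10 and Ψ differed by at least 0.1. As a second reading of the same pools, inclusion and skipping reads were compared by a two-sided Fisher's exact test per exon with Benjamini-Hochberg adjustment over the tested exons. That test compares those libraries, not the conditions.

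The criteria, the alternatives, the gene lists and the rule for named exons were fixed before the data were examined, apart from the alternatives named in the closing section as chosen later. Named exons were the 12 with the largest difference in each direction among called exons with at least 20 isoform-specific reads per group, 1 per gene. To these were added up to 3 called exons per direction from each of 10 gene lists with 848 genes, and the best-covered exons of PLEC, ERRFI1 and SNRPA1. Of the exons this rule selects, 1 is not reported here. The lists covered epithelial-mesenchymal splicing switches, SR proteins and hnRNPs with other splicing regulators, the core spliceosome, cytoskeleton and adhesion, programmed cell death, RNA sensing and the interferon response, cell cycle, DNA repair, chromatin regulators, and markers of other cell types. The median difference of each list was ranked among 10000 random sets of tested exons matched on read number in 10 bins. The same was done for features of the called exons. The GC content of flanking introns was not analysed here.

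For the closing section, Ψ and Bayes factors were recomputed from the deposited reads with a 2-isoform likelihood. A read length of 76 nt came closest to the deposited Ψ among the lengths tried, with a Pearson correlation across exons of 0.997 in the SSE mimetic group and 0.999 in the scrambled group. The model was run on the reads as deposited, after subtraction of the read density of the flanking introns, and after thinning of the scrambled reads to the SSE mimetic number. The intron read density was the number of reads matching neither isoform over the length of both flanking introns. It can therefore include spliced reads and reads of other exons within those introns. Only 22.6% of tested exons had flanking introns that held no other annotated exon. It was tested on simulated data at the real depth of the SSE mimetic against scrambled comparison with 8228 exons. It called 42% of exons raised by 0.2, 24% of those lowered by 0.2, 68% of those raised by 0.4 and 54% of those lowered by 0.4. Of 8028 unchanged exons, 0.262% were called. These simulated reads held no intron background, so that rate does not cover calls that background can produce. Other simulations, with background and no change in splicing, gave 307 to 342 higher and 49 to 65 lower calls. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.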

Results

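The deposited tables describe cassette exons in MDA-LM2 breast cancer cells that received the SSE mimetic or a scrambled oligo, with 2 samples pooled in each group. The SSE mimetic summary listed 46629 events and the scrambled summary 47968. The groups differed in depth and in the kinds of reads. Over the 45977 events in both summaries, where a read can count for more than 1 event, isoform-specific reads numbered 431105 in the SSE mimetic group. They numbered 2039336 in the scrambled group, a ratio of 4.73, while for reads that matched neither isoform the ratio was 1.54. Reads that matched neither isoform of their event made up 95.3% of reads in the SSE mimetic group (34676430 of 36383901) and 88.8% in the scrambled group (53271172 of 59995829). A tested exon had a median of 19 isoform-specific reads in the SSE mimetic group and 78 in the scrambled group. The median width of the 95% credible interval of Ψ was 0.35 and 0.15, respectively. All Ψ values below are the authors' values for 1 pooled read set per group, given with these credible intervals, and no replicate spread can be attached to them.

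The comparison asked whether an RNA that mimics the SSE, the structured splicing enhancer at the centre of the study, alters exon inclusion. A long coding exon of PLEC, which encodes the rod of the cytoskeletal linker plectin, had a Ψ of 0.41 (0.38 to 0.44) with the SSE mimetic and 0.88 (0.86 to 0.90) with the scrambled oligo. An exon of STX2, a syntaxin gene with a known epithelial-mesenchymal splicing switch, was higher with the SSE mimetic, at 0.91 (0.75 to 0.99) against 0.40 (0.32 to 0.49). Exons of the histone methyltransferase genes EZH2 and SETD2 were also higher, at 0.54 (0.33 to 0.77) against 0.09 (0.06 to 0.13) and at 0.62 (0.47 to 0.76) against 0.17 (0.12 to 0.21). In all, 255 exons in 222 genes were called higher and 73 exons in 69 genes were called lower with the SSE mimetic, among 8228 tested exons in 4633 genes. The other 7900 tested exons did not pass the criteria.

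The PLEC exon lies on chromosome 8 from 143922504 to 143925884 in hg38, on the minus strand, and is 3381 nt long. It is followed by a downstream exon of 7243 nt. In the authors' deposited table its Bayes factor stood at the cap of 1e12. It had 956 inclusion reads, 1 skipping read and 5026 shared reads in the SSE mimetic group, and 8883, 12 and 21445 in the scrambled group. Shared reads per inclusion read were thus 5.26 and 2.41. The share of inclusion reads among isoform-specific reads was 0.999 in both groups, and Fisher's exact test on these reads gave an adjusted p of 1.

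**Figure D1:**
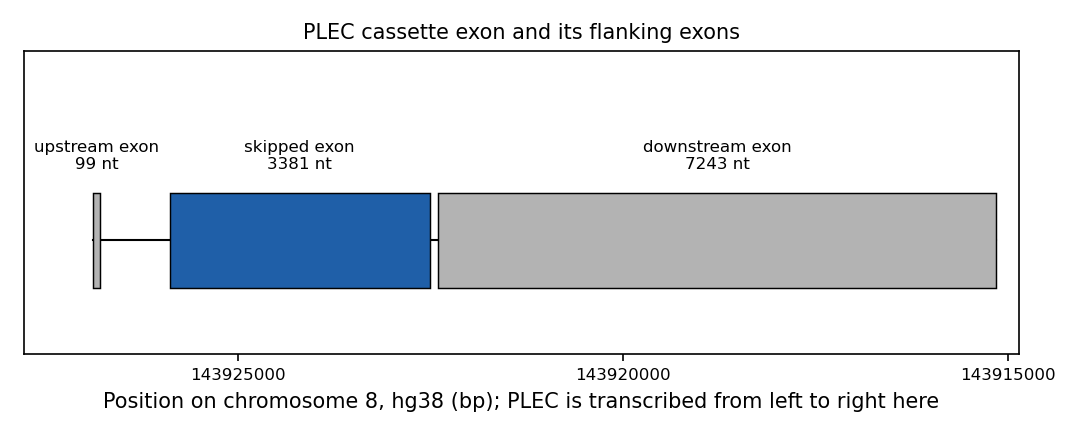
The PLEC cassette exon and its flanking exons are drawn to scale along chromosome 8 of hg38 (horizontal axis, position in bp), with the direction of transcription from left to right. Boxes are exons and the line marks introns. The skipped exon of 3381 nt (blue) lies between an upstream exon of 99 nt and a downstream exon of 7243 nt (grey).

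Of the other genes chosen in advance, ERRFI1, which encodes a feedback inhibitor of EGFR, had a Ψ of 0.11 (0.04 to 0.21) with the SSE mimetic and 0.32 (0.23 to 0.40) with the scrambled oligo for a coding exon on chromosome 1 from 8015308 to 8015384. In the authors' deposited table its Bayes factor was 33.46 and its difference -0.21, which pass the Bayes factor and size set for a call. It had 4 inclusion reads, no skipping read and 1582 shared reads in the SSE mimetic group. In the scrambled group these were 42, 0 and 5021. The exon fell short of the minimum of isoform-specific reads in the SSE mimetic group alone, and for that reason was not tested. An exon of SNRPA1, which encodes a protein of the U2 small nuclear ribonucleoprotein, had a Ψ of 0.89 (0.68 to 0.98) against 0.95 (0.89 to 0.99). It lies on chromosome 15 from 101286214 to 101286293. Its Bayes factor in the authors' deposited table was 0.18, and it was not called. The difference recomputed with a 2-isoform model was -0.0381, and 0.101 with the scrambled reads thinned to the SSE mimetic number, not called in either.

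Among exons called higher with at least 20 isoform-specific reads per group, the largest differences reported here were in MOK, a kinase gene, and COL4A3BP. The latter encodes the ceramide transfer protein. The MOK exon (chromosome 14, 102225095 to 102226408) had a Ψ of 0.76 (0.51 to 0.99) with the SSE mimetic and 0.15 (0.11 to 0.18) with the scrambled oligo. The COL4A3BP exon (chromosome 5, 75400205 to 75403058), found in a noncoding transcript, had 0.89 (0.62 to 0.99) and 0.29 (0.19 to 0.42). Exons of SORBS2, TROAP, AFTPH, PCID2, TBCE, PRC1, HNRNPC, PFDN5 and TUG1 differed by 0.53 to 0.59. PRC1 encodes a protein that bundles microtubules of the spindle midzone, HNRNPC binds nascent transcripts, and TUG1 is a long noncoding RNA. The HNRNPC exon (chromosome 14, 21211406 to 21211563) was at 0.70 (0.57 to 0.84) against 0.16 (0.14 to 0.18). The PRC1 exon (chromosome 15, 90983906 to 90984140) was at 0.79 (0.59 to 0.97) against 0.24 (0.21 to 0.27), with 348 inclusion reads and no skipping read in the scrambled group. After subtraction of the intron read density, the recomputed difference fell from 0.633 to 0.275 for MOK and from 0.601 to 0.359 for AFTPH, both still called, and rose from 0.539 to 0.822 for HNRNPC. The PCID2 exon was then no longer called (0.566 before, 0.411 after), nor was the PFDN5 exon, which had no read left in the SSE mimetic group. With thinned scrambled reads the TROAP exon was not called (0.601 before, 0.461 after).

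Among exons with at least 20 isoform-specific reads per group, the largest fall in Ψ was in HDLBP, which encodes the RNA-binding protein vigilin. Its coding exon (chromosome 2, 241255374 to 241255580) had a Ψ of 0.32 (0.21 to 0.45) with the SSE mimetic and 0.96 (0.88 to 1.0) with the scrambled oligo. WDR45B, an autophagy gene, had an exon at 0.23 (0.14 to 0.34) against 0.84 (0.71 to 0.95), on chromosome 17 from 82630921 to 82631022. An exon of ANXA5, which encodes the phospholipid-binding annexin A5, was at 0.47 (0.37 to 0.58) against 0.98 (0.95 to 1.0), on chromosome 4 from 121684677 to 121684771. The coatomer gene ARCN1 (chromosome 11, 118581246 to 118581509) was at 0.46 (0.37 to 0.57) against 0.97 (0.93 to 0.99). The proteasome gene PSMA4, the ETS factor gene ELK3, the actin-capping gene CAPZA2 and PDLIM5 had differences between -0.53 and -0.44. With thinned scrambled reads the recomputed difference went from -0.531 to -0.287 for PSMA4 and from -0.491 to -0.348 for ELK3, and neither was called. Exons of RPL9, BTF3 and HSP90AA1 differed by -0.58, -0.51 and -0.45. Subtraction of the intron read density moved the recomputed difference from -0.588 to -0.952 for RPL9 and from -0.449 to -0.747 for HSP90AA1. Reads shared with processed pseudogenes, which are known for these genes and for HNRNPC and HNRNPA3 among others, were not examined here.

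**Figure D2:**
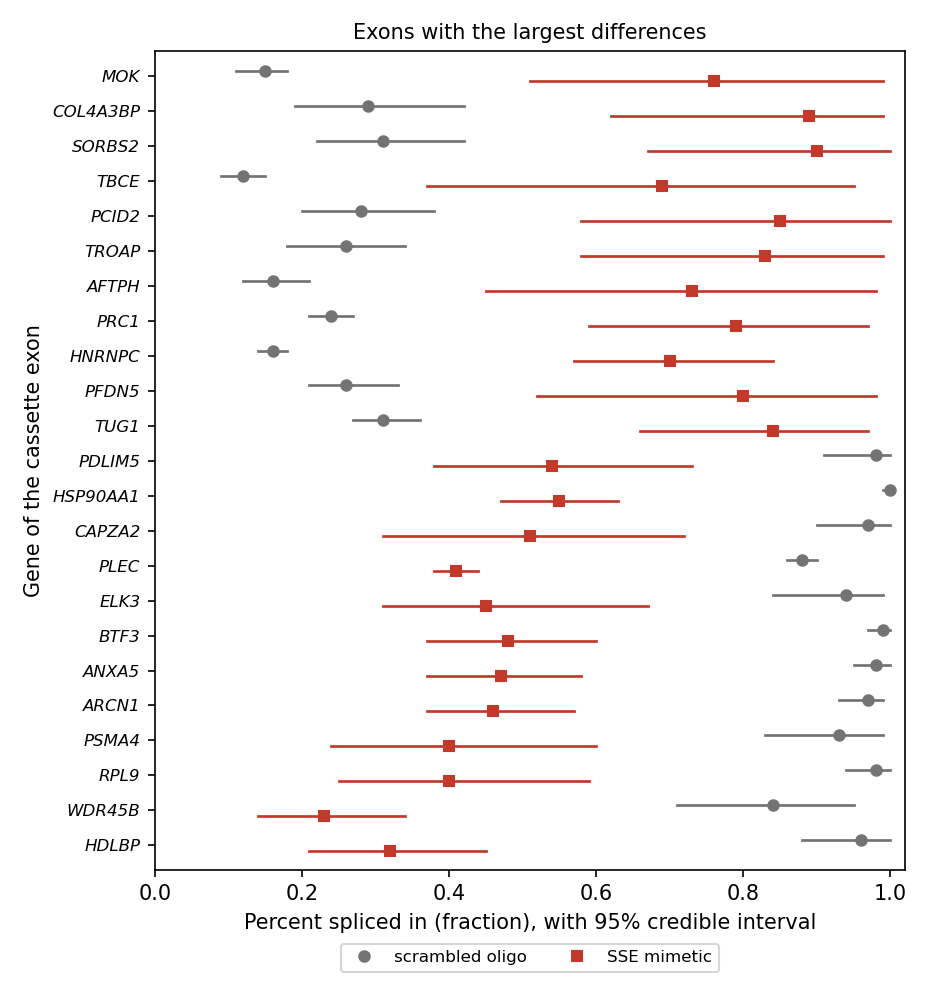
Percent spliced in (horizontal axis, fraction) of the 23 named exons with the largest differences, labelled by gene on the vertical axis. Grey circles are the scrambled group, red squares the SSE mimetic group, and lines the authors' 95% credible intervals. The intervals of the 2 groups are apart for each exon shown, from MOK (0.51 to 0.99 against 0.11 to 0.18) to HDLBP (0.21 to 0.45 against 0.88 to 1.0).

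Exons called higher made up 77.7% of the called exons (95% Clopper-Pearson interval 72.8 to 82.1). Their median Ψ was 0.60 with the SSE mimetic and 0.17 with the scrambled oligo, and the credible intervals were apart for 244 of 255. Exons called lower had a median Ψ of 0.46 and 0.94, and the intervals were apart for 69 of 73. Over all tested exons the median difference was -0.03 (interquartile range -0.09 to 0.03), with 5200 exons below 0 and 2749 above. Exons simulated without a change at the same depth had a median of -0.0216 in the 2-isoform model, which gave -0.0267 on the deposited reads and 0 with the scrambled reads thinned to the SSE mimetic number. Among exons with a mean Ψ of 0.1 to 0.5, the median difference was 0.13, with 167 called higher and 11 lower. Among those with a mean Ψ of 0.5 to 0.9 it was -0.06, with 79 higher and 61 lower. Exons simulated without a change were not split by mean Ψ, so whether lower depth gives the same pattern was not tested.

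**Figure D3:**
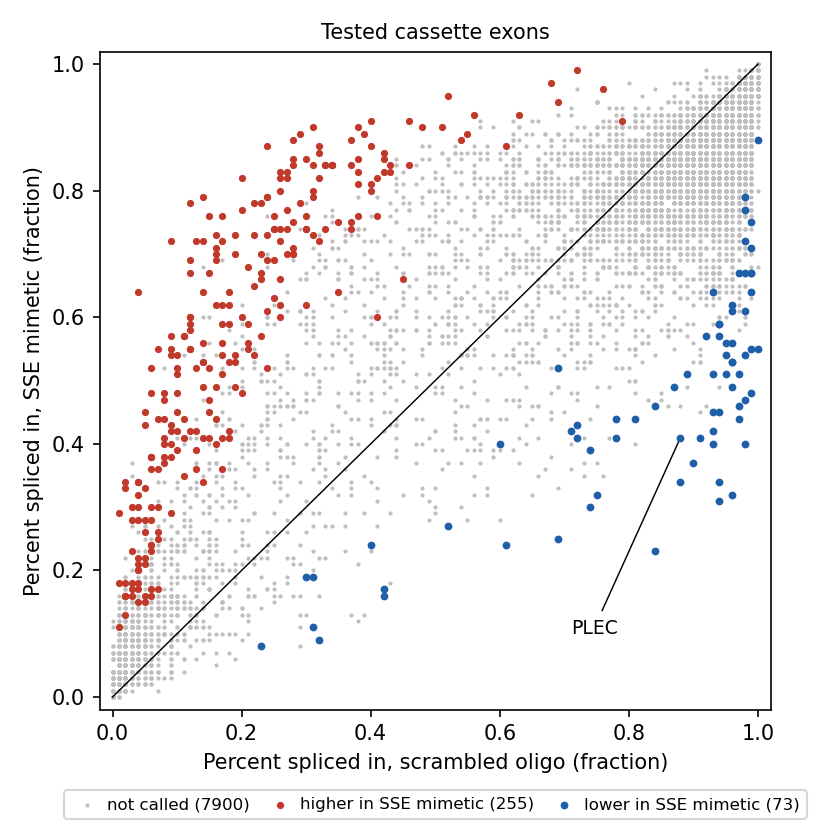
Percent spliced in of the 8228 tested exons in the scrambled group (horizontal axis, fraction) and the SSE mimetic group (vertical axis, fraction), with 1 point per exon and the line of equal values. Red points are the 255 exons called higher, blue points the 73 called lower, and grey points the 7900 exons that did not pass the criteria. The red points lie mostly at low scrambled values (median 0.17) and the blue points mostly at high ones (median 0.94). Since Ψ is bounded at both ends, the criteria for a call favour this placement.

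The share of inclusion reads was larger with the SSE mimetic in 211 of the 255 exons called higher, STX2, EZH2 and SETD2 among them, and smaller in 0. In the other 44 it was equal, with no skipping read in either group. These included the exons of MOK, TROAP, AFTPH, TBCE, PFDN5 and TUG1 and both PRC1 exons, and the HNRNPC exon had 2 skipping reads with the scrambled oligo and 0 with the SSE mimetic. Fisher's exact test on reads passed for 61 of these 255 exons. The adjusted p was 0.00535 for STX2, 0.0102 for EZH2 and 0.0362 for SETD2. Of the 73 exons called lower, PLEC and HDLBP among them, 56 had no skipping read in the SSE mimetic group and 47 had none in either group. Of all 8228 tested exons, 4509 had none in either group, and such exons cannot pass Fisher's exact test. The share of inclusion reads was smaller with the SSE mimetic in 16 of the 73, equal in 47 and larger in 10, and none passed Fisher's exact test. Over all tested exons, that test passed for 83 after adjustment and for 453 at an unadjusted p under 0.05. The inclusion share was larger with the SSE mimetic in each of the 83. Unspliced reads inside a skipped exon would count as inclusion reads here too, so this test does not separate background from splicing. With this test in place of the Bayes factor, 67 exons were called higher and 0 lower. With the inclusion share in place of Ψ, 190 were higher and 6 lower. With a Bayes factor of at least 100, 126 exons were called higher and 38 lower, and the calls of DDX39B, PPIE, ADAR, both GBP3 forms, BIRC2, ZYX, ELK3, HNRNPA3, ING4, MBNL1 and the 5′ UTR exon of HNRNPC ended.

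Over all tested exons 3.99% were called, 77.7% of them higher, and the number of calls in a list was not tested against these shares. In genes with known epithelial-mesenchymal splicing switches, 104 exons in 30 genes were tested, of which 2 were called higher, 2 lower and 100 did not pass. The list was matched by gene, so these were any tested cassette exons of the genes. Whether the called exons are the switch exons was not examined. Besides STX2 on chromosome 12 (130795995 to 130796120), an exon of the amyloid precursor-like gene APLP2 was higher, at 0.82 (0.69 to 0.91) against 0.41 (0.36 to 0.47). Exons of SEC31A, a COPII coat gene, and MBNL1, a splicing regulator, were lower, at 0.34 (0.17 to 0.55) against 0.94 (0.82 to 1.0) and at 0.56 (0.32 to 0.83) against 0.96 (0.88 to 1.0). MBNL1 was not called by the 2-isoform model in any of its 3 settings (differences of -0.381 on the reads as deposited, -0.395 after subtraction and -0.301 after thinning). STX2 was the 1 exon of this list that passed Fisher's exact test on reads, both over all exons and adjusted over the list alone.

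Among SR proteins, hnRNPs and other splicing regulators, 7 of 145 exons were called higher, 4 lower and 134 did not pass. The higher ones included HNRNPA3 (0.83, 0.60 to 0.97, against 0.42, 0.30 to 0.56) and a second form of the HNRNPC exon, 21211406 to 21211566, which overlaps the one above (0.86, 0.72 to 0.97, against 0.32, 0.29 to 0.35). Subtraction of the intron read density moved the recomputed difference of this form from 0.544 to 0.853, and thinning moved that of HNRNPA3 from 0.458 to 0.219, where it was not called. The lower ones included HNRNPH1 (0.27, 0.22 to 0.33, against 0.52, 0.48 to 0.56) and an exon in the 5′ UTR of HNRNPC (0.19, 0.14 to 0.23, against 0.31, 0.28 to 0.34). Fisher's exact test on reads passed for 1 exon over all exons and 2 adjusted over the list alone. The core spliceosome had 2 of 60 exons called higher, 0 lower and 58 that did not pass. These were in the RNA helicase gene DDX39B (0.18, 0.09 to 0.30, against 0.04, 0.02 to 0.06) and the cyclophilin gene PPIE (0.17, 0.12 to 0.24, against 0.07, 0.05 to 0.09). The DDX39B exon had 8 inclusion and 13 skipping reads with the SSE mimetic and 20 and 326 with the scrambled oligo, with an adjusted Fisher p of 0.00929. After subtraction of the intron read density, the recomputed differences of the DDX39B and PPIE exons fell from 0.135 and 0.102 to 0.0275 and 0.0022, and neither was called. Fisher's exact test passed for 1 core spliceosome exon over all exons and 3 adjusted over the list alone.

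Cytoskeleton and adhesion genes had 7 exons called higher, 9 lower and 181 that did not pass. The higher exons included CLIP1, whose protein tracks growing microtubule ends (0.36, 0.25 to 0.50, against 0.07, 0.06 to 0.09, adjusted Fisher p 0.00063), and ZYX, which encodes the focal adhesion protein zyxin (0.59, 0.31 to 0.91, against 0.18, 0.10 to 0.29). After subtraction of the intron read density, the recomputed CLIP1 difference fell from 0.281 to 0.150 and was still called. The ZYX exon was not called after subtraction, with no read left in the SSE mimetic group, or after thinning (0.444 before, 0.393 after). The lower exons included PLEC, PDLIM5 and CTNNA1, which encodes alpha-catenin (0.37, 0.21 to 0.56, against 0.90, 0.76 to 1.0). In this list, 3 exons passed Fisher's exact test, both over all exons and adjusted over the list alone. Of these, CLIP1 was named by the rule, while ITGB1 and ARPC4 are named here after their values were seen.

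Chromatin regulators had 6 exons called higher, 1 lower and 164 that did not pass. Besides EZH2 and SETD2, the higher exons included ING4 (0.67, 0.43 to 0.91, against 0.23, 0.12 to 0.43), and the lower one was in SMARCB1, a SWI/SNF subunit gene (0.41, 0.20 to 0.70, against 0.91, 0.75 to 0.98). The credible intervals of ING4 meet, and SMARCB1 was not called with thinned scrambled reads (-0.514 before, -0.416 after). On reads, 3 chromatin exons passed Fisher's exact test, over all exons and adjusted over the list alone, in EZH2, SETD2 and BPTF, the last named after its values were seen. Cell cycle genes had 7 exons called higher, 0 lower and 141 that did not pass, and included CEP57 (0.72, 0.42 to 0.99, against 0.13, 0.07 to 0.21) and a further PRC1 exon that also lies in a second annotated gene (0.90, 0.75 to 0.98, against 0.51, 0.47 to 0.56). RNA sensing and interferon genes had 3 higher, 0 lower and 44 that did not pass. The 3 were an exon of the RNA-editing gene ADAR (0.55, 0.23 to 0.87, against 0.09, 0.04 to 0.15) and 2 overlapping forms of 1 exon of GBP3. After subtraction, neither ADAR (recomputed difference 0.469 before, 0.272 after) nor the longer GBP3 form (0.432 before, 0.322 after) nor CEP57 (0.598 before, 0.407 after) was called, and the shorter GBP3 form was not called after thinning (0.422 before, 0.311 after). Of the cell death exons, 1 was called lower and 81 did not pass. It lies in the 5′ UTR of the apoptosis inhibitor gene BIRC2 (0.53, 0.30 to 0.84, against 0.96, 0.87 to 1.0), and was not called after subtraction (-0.429 before, -0.539 after) or thinning (-0.399). Fisher's exact test passed for 2 other cell death exons, over all exons and adjusted over the list alone, in BCL2L1 and PDCD10, which are named after their values were seen. None of 95 DNA repair exons and none of 11 exons of other-cell-type markers was called, and Fisher's exact test passed for 0 exons in the DNA repair, cell cycle, RNA sensing and other-cell-type lists, over all exons or adjusted over the list alone.

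By median difference, 3 lists stood above random sets of exons with like read numbers. These were the core spliceosome (0, percentile 99.98, random sets -0.06 to -0.02), the splicing regulators (-0.01, percentile 99.9) and the epithelial-mesenchymal list (-0.01, percentile 99.6). With random sets matched on mean Ψ as well, the percentiles were 82.1, 61.0 and 40.9, so none of the 3 stood apart. With 1 exon per gene, the epithelial-mesenchymal list lay at percentile 90.7 (median -0.02), and with at least 20 isoform-specific reads the chromatin regulators rose to percentile 98.6 (median -0.01). The other lists lay between percentile 4.86 (other cell types, median -0.07) and 94.6 (cytoskeleton and adhesion, median -0.02). Cell death, DNA repair, chromatin, RNA sensing and cell cycle genes had medians of -0.05, -0.05, -0.04, -0.03 and -0.03. Several calls in a list came from the same gene or from exons with fewer reads. With 1 exon per gene, the one with most reads, the called exons numbered 8 for cytoskeleton and adhesion, 4 for splicing regulators, 3 for chromatin, 2 for the core spliceosome, 1 each for the epithelial-mesenchymal, cell cycle and RNA sensing lists, and 0 for cell death.

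Exons called higher were long, with a median of 219 nt against 145 to 173 nt in random sets matched on read number. They lay in coding sequence in 56.9% of cases against 69.8% to 80%. With matching on mean Ψ as well, the length still stood apart (166 to 199 nt) and the coding share lay at percentile 3.78. Of the 255, 3 were 75 nt or shorter, 1.18% against 9.42% of all tested exons. Exons called lower had a median length of 160 nt against 123 to 171 nt, and 86.3% were coding against 74.0% to 91.8%. Relative to the summed length of their flanking exons they lay within random sets matched on read number (median 0.484 against 0.409 to 0.615). They were short in these terms only when mean Ψ was matched as well (0.525 to 0.832), and lay at percentile 57.7 with at least 20 isoform-specific reads. Exons called higher were long in the same terms under both matchings (0.718 against 0.474 to 0.588 and 0.533 to 0.684). The GC content of exons called higher was 46.6% (233 of 255 with a value), at percentile 8.44 of random sets and 0.62 with matching on mean Ψ, and at percentile 1.45 with at least 20 isoform-specific reads (45.1%). Both sets lay within the range of random sets matched on read number for the share of exons with a length that is a multiple of 3 (45.1% and 50.7%), for microexons of 27 nt or shorter (0%), and for the median upstream (1834 and 1644 nt) and downstream intron (2170 and 1870 nt). With at least 20 isoform-specific reads, the share of multiples of 3 among exons called lower was 57.8%, at percentile 97.8 and so outside that range.

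Since each group was pooled, these calls compare 2 read sets, and whether a difference exceeds the spread between samples cannot be tested. Called exons of low depth, such as those of ADAR with 10 isoform-specific reads in the SSE mimetic group, have wide intervals. At this depth the 2-isoform model called 42% and 68% of simulated rises of 0.2 and 0.4. For falls of 0.2 and 0.4 it called 24% and 54%, so an exon that did not pass may still have changed.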

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

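The summary of the SSE mimetic group lists 652 events that the scrambled summary does not, and the comparison of the groups therefore does not use them. Of these, 10 had more than 3 isoform-specific reads, the number that a count of 0 allows, and the highest had 5. In the scrambled summary, 1991 events were listed alone, 415 of them above that number, and the highest had 36. No explanation was tested for these events.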

How the results depend on the processing

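The tests with the 2-isoform model and the one that also asks for a like shift in the inclusion share were chosen after the data were seen. In every alternative run, more exons were called higher than lower, but the number of lower calls depended on how skipping reads were used. With a Bayes factor of at least 100, 126 exons were higher and 38 lower. With at least 20 isoform-specific reads these were 139 and 45, and with at least 50 they were 49 and 23, with 68.1% higher and a median difference of -0.02. With at least 5 reads, 115 were lower, and with no minimum 430 were higher and 214 lower, with 66.8% higher and a median of 0. With Fisher's exact test in place of the Bayes factor, 67 were higher and 0 lower (100% higher). With the share of inclusion reads as the size, 6 were lower, 96.9% were higher and the median was 0. Small differences of opposite sign from Ψ then appeared in PLEC (0.000304), ANXA5 (0.00203) and HNRNPH1 (0.0012). Most of the lower calls have no skipping read, so these read-share alternatives cannot call them. Asking for a like shift in the share left 16 lower calls and 93.0% higher. The 2-isoform model gave 82.7% higher and a median of -0.0267, after subtraction of intron density 70.0% and -0.0255, and after thinning 41 lower calls and a median of 0. Higher calls numbered 320 in the model, 250 after subtraction and 187 after thinning, and lower calls 67, 107 and 41, so subtraction lowered the share of higher calls partly by adding lower calls. Of the authors' 255 higher and 73 lower calls, the model called 247 and 51 on the reads as deposited and 156 and 34 after thinning. Where no cause is given, the cause was not tested. Of 47 named and tested exons, 37 gave the same verdict after subtraction, 38 after thinning and 6 under Fisher's exact test. Calls of named exons that ended on subtraction or thinning or at a Bayes factor of at least 100 are given in the report, while for Fisher's exact test (41 calls ended) and the share of inclusion reads (34 ended, 3 of opposite sign) only the counts are given for most exons. Where PCID2, ADAR, the longer GBP3 form, CEP57 and BIRC2 lost theirs on subtraction, a difference of at least 0.1 remained and the Bayes factor of the model was under 10. Of 127 higher calls of the model lost on subtraction, 7 had no read left in the SSE mimetic group, and 71 others had a difference under 0.1. With 1 event per exon, reads of neither isoform were 94.8% and 87.6%. No paired analysis was possible because the columns carry no replicate, and leaving out a sample could not be run for the same reason. Depth limits chiefly the SSE mimetic group.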

Other observations

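The tests of skipping-read numbers and of other read lengths and overhangs, of the share of higher calls after subtraction, of subtraction in exons whose introns hold no other annotated exon, of subtraction and thinning combined and of which exons the simulations called were chosen after the results were seen, and the bound for the share of higher calls was set after the simulated values were seen, in place of one on higher minus lower calls that the data had passed. Some exons that were not called by Ψ passed Fisher's exact test on reads, and 2 of them are described here. An exon in the 5′ UTR of HNRNPC (chromosome 14, 21262601 to 21262768) had 23 inclusion and 40 skipping reads with the SSE mimetic and 37 and 445 with the scrambled oligo. An exon of BCL2L1, which encodes the apoptosis regulator Bcl-x, had 9 and 7 against 8 and 73 (chromosome 20, 31666991 to 31667147, adjusted p 0.0188). Over all events, skipping reads made up 11% of isoform-specific reads in the SSE mimetic group and 16.3% in the scrambled group. Both exons were singled out after their values were seen.

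The first pattern is the excess of higher over lower calls. Lower depth alone did not account for it, since at most 5 higher calls arose in 20 simulations with unchanged splicing, against 320 from the 2-isoform model. Unspliced RNA or DNA that adds reads inside long exons could raise Ψ: simulations with background and depth but no change in splicing gave 307 to 342 higher calls, and 66 of the 255 exons called higher were called so in most of them (8.21 by chance). Subtraction of the intron read density left 60.3% of the model's higher calls (193 of 320, 95% Clopper-Pearson interval 54.7 to 65.7) against 18.2% to 27.5% in those simulations, and 58.0% (47 of 81, 46.5 to 68.9) against 14.8% to 29.3% in exons whose introns hold no other annotated exon, where CLIP1, EZH2, SETD2, TBCE and HNRNPA3 stayed and ADAR and PPIE did not; higher calls then outnumbered lower ones by 143 (250 against 107) where the simulations gave 41 to 81, although the share of higher calls, 70.0% (65.0 to 74.7), was not above the simulated 72.5% to 84.3%, and 31.6% of the 320 stayed with thinning added. How much of the excess is background stays open, because these bounds assume that background in exons has the intron density: background and a change in splicing cannot be told apart exon by exon, and while the 255 exons had 11935 skipping reads with the scrambled oligo where Ψ and the inclusion reads would need 14121 (7630 to 22741 at other read lengths and overhangs), and 1075 with the SSE mimetic where 1194 would be needed, 44 of them, such as MOK and PRC1, had 0 with the scrambled oligo where 2789 would be needed (1538 to 4415), so that the low Ψ of these 44 does not rest on skipping reads.

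The second pattern is the set of exons called lower, PLEC among them. Lower depth alone gave at most 8 lower calls in 20 simulations (mean 3.4), against 67 from the model. That highest number missed the bound set beforehand for setting depth aside. Depth alone thus fell well short of the number of lower calls, but was not excluded for a few of them. By a reading added later, 0 exons were called lower in most of those simulations. After subtraction of the intron read density, 88.1% of the model's lower calls stayed (59 of 67). That step also takes reads from the skipped exon, and lower calls rose from 67 to 107. It therefore cannot exclude background in the flanking exons, and it assumes that background in exons has the intron density. Simulations with background and depth but no change in splicing gave up to 65 lower calls, so their number alone does not set background aside. In most of them 36 exons were called lower, and 0 of the 73 were among these 36 (0.319 by chance). That overlap says nothing of exons called in fewer simulations. With subtraction and thinning combined, 46 of the model's 67 lower calls stayed, under the same limit. Direct joining of the flanking exons at the size that Ψ gives is also argued against: the 73 exons had 52 skipping reads with the SSE mimetic (95% Poisson interval 38.8 to 68.2) where Ψ and the inclusion reads would need 1361 at the inferred read length of 76 nt (770 to 2078 at lengths of 36 to 150 nt or longer overhangs), exons not called had 118% and 139% of the number needed in the SSE mimetic and scrambled groups, and the shortfall was there with the scrambled oligo too (157 where 2611 would be needed), so it was not specific to the SSE mimetic. A smaller rise in skipping stays open for the 16 of 73 lower calls with a larger share of skipping reads, and what raised shared over inclusion reads in the others, such as other transcript ends or uneven coverage along transcripts, was not tested.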
